A study of Mus musculus and Homo sapiens with 83 samples.

How the data were processed

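The series holds 83 arrays of total RNA from lung tissue, 39 human arrays of the type HG_U95Av2 and 44 mouse arrays of the type MG_U74Av2, and per the labels each array is tumor or adjacent normal lung. The deposited values are signal intensity per probe set, in linear units (intensity), scaled so that the mean without the lowest and highest 2% of probe sets is 500.2 to 500.3 on each array. The sources used here name no software, background correction or probe summary. No value was below 0, and 2 mouse values equaled 0. The files of the mouse arrays also gave the day of scanning, which was read as a batch number from 1 to 6, and those of the human arrays gave none.

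Signals were kept as deposited, 16 was added and the log2 taken. Control probe sets (67 human, 66 mouse), those with no gene symbol in the table given (1070 and 1193) and those with several (545 and 396) were left out of the gene fit, as were XIST and Y-linked genes in human. A gene with several probe sets was read from the one with the highest mean log2 signal, which left 8210 human and 8251 mouse genes. Human arrays of the same subject number and tissue were averaged before the fit.

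Groups were compared with limma 3.58.1 (lmFit and eBayes with trend) in R 4.3.3, with Benjamini-Hochberg adjustment over genes, and a gene was called at an adjusted p under 0.05. The human fit held 10 tumor and 10 adjacent means, without a block. All 4 mouse groups entered 1 fit, from which the tumor changes at 24 to 26 and 42 weeks, their difference and the age differences within each tissue were taken. All changes are log2 tumor minus adjacent, or 42 minus 24 to 26 weeks, with the standard error of limma's fit. In mouse the number of arrays that shows a direction is the number of tumor values beyond the median of adjacent lung. In human the naming rule counted the subject numbers whose tumor mean differed from their own adjacent mean in that direction. For lists compared between species, human tumors were instead counted against the mean of adjacent lung.

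Gene lists, 36 in number with 891 entries, were fixed before the data were examined, as were the comparisons, the tests and most other settings. They were tested with camera with an estimated correlation between the genes of a list, adjusted over the 36 lists of a comparison, and with a preset correlation of 0.01. Fry, added later, tests whether the genes of a list move one way on balance. Named genes were chosen by a rule fixed beforehand. In each tumor comparison it takes the 12 largest rises and 12 largest falls among called genes with at least 2-fold change, a signal above the median of all genes in the higher group, and the same direction in at least 9 of 10 subjects or 90% of mouse tumor arrays. For age comparisons it takes the 8 largest each way, and across species the 12 each way with the largest of the smallest changes. From each list it allows up to 4 members with the smallest p, and members of interest as values.

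Species were compared over 4889 genes paired by the same symbol, with rank correlation across genes and counts of genes called the same way. The difference between species in a list's mean change was tested by permutation, two-sided: each group was centered on its mean, and tumor and adjacent labels were drawn anew 100000 times among the human values and within each mouse age. Other settings were pseudocounts of 1 and 64, quantile normalization, centering on the median, leaving out the dimmest 40% of genes, the mean over probe sets, all probe sets, robust eBayes, the scan day, the AJ or LZ prefix and the human subject number as blocks, LZ or AJ arrays only, and leaving out the Tq arrays. Added after seeing the data were fits within each scan day, combinations of these with the Tq arrays left out, fry, the test between species and the count of opposite genes.

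The test was tried on simulated data with normal, independent genes that had the spread of the real arrays, 200 of which carried a known change. In the human design limma recovered 25.4% of changes of 0.5 log2 units, 86.6% of changes of 1 and 97% of changes of 2, and 3.5% of calls were false. For the mouse change at 24 to 26 weeks recovery was 55.2%, 97% and 100%, and for the difference of changes between ages 20.9%, 62.7% and 98.5%. Camera called the 1 list shifted by 1 log2 unit and 0 of 35 random lists. The genes of these lists were independent, so this trial does not cover lists whose genes correlate. The human cell cycle list, for example, had an estimated correlation of 0.60. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and mouse gene positions were read from the RefSeq table of GRCm38.p6. Human positions were not in the files.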

Results

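Messenger RNA levels were measured in lung tumors and adjacent normal lung of humans and of mice on oligonucleotide arrays, which read each transcript as a hybridization signal. The human part held 39 arrays, 20 of tumor and 19 of adjacent normal lung, and their titles carried 10 subject numbers. Arrays of the same number and tissue were averaged, which gave 10 tumor and 10 adjacent values per gene. The mouse part held 44 arrays: 8 of adjacent lung and 12 of tumor labeled 24 to 26 weeks, and 7 of adjacent lung and 17 of tumor labeled 42 weeks. The labels do not say from what event the weeks are counted, so age stands below for these labeled weeks. All deposited signals were intensities scaled to a trimmed mean of about 500.2 per array. The median signal ran from 179.7 to 208.6 over the human arrays and from 154.1 to 212.8 over the mouse arrays. All changes are on the scale of log2(signal + 16), which understates those of dim genes. The number of arrays limits the precision. Mouse titles began with AJ or LZ, codes that the labels do not explain, and 2 tumor titles, 1 at each age, ended in Tq.

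Human tumors were set against adjacent normal lung, the contrast that the labels give. Many genes of the lung's gas exchange surface, its vessels and its resident connective tissue fell, while many of the cell cycle, tumor stroma matrix, and epithelial and carcinoma lists rose. Of these lists only the last passed camera with an estimated correlation, as given below. Among the largest rises was that of SPP1 (osteopontin, a secreted matrix protein), by 4.05 ± 0.42 log2 units (± SE), from an adjacent signal of 1110.4 ± 1295 to 13173 ± 6387 in tumors (SD, n = 10 each). AGER, a receptor abundant in alveolar type I cells, fell by 3.96 ± 0.51 log2 units, from 13613 ± 4448 to 1368 ± 1090.4 (SD, n = 10 each). In all, 1991 of 8210 genes passed limma's test at an adjusted p under 0.05, 982 higher and 1009 lower in tumors. At least 2-fold changes numbered 221 higher and 368 lower.

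Among the other genes with the largest rises, several belong to matrix and secretion. SPINK1, a secreted trypsin inhibitor, rose by 3.85 ± 0.72 (adjusted p = 0.00048, 9 of 10 subject numbers). COL11A1, a fibrillar collagen chain, rose by 3.83 ± 0.67, from 12 ± 2.56 to 863 ± 854 (SD, n = 10 each). SULF1, which edits heparan sulfate outside cells, rose by 2.38 ± 0.50, and PTGES, a prostaglandin E2 synthase, by 2.36 ± 0.31. PYCR1, an enzyme of proline synthesis, rose by 2.57 ± 0.25 and RAMP1, a partner of the calcitonin-receptor-like receptor, by 2.41 ± 0.30. The transcription factors TFAP2A and ETV4 rose by 2.53 ± 0.47 and 2.46 ± 0.30, but the 2 other probe sets of TFAP2A stood at 0.0239 and 0.0259. The tumor stroma matrix list held SPP1 and COL11A1: 16 of 24 measured genes rose and 0 fell (adjusted over the list alone, 17 and 1; adjusted p = 0.21 with an estimated correlation). Named genes with a mean under 50 in adjacent lung moved further with 1 added to the signal and less with 64, so their size and order are set partly by that number: COL11A1 (4.74 and 2.77), TFAP2A (3.04 and 1.82) and KIF23 (1.99 and 0.55). COL10A1, another collagen chain, rose by 1.91 ± 0.25 and FAP, a protease of activated fibroblasts, by 1.62 ± 0.25.

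Most measured mitosis genes rose. UBE2C and CDC20, a ubiquitin-conjugating enzyme and an activator of the anaphase-promoting complex, rose by 3.56 ± 0.52 and 2.68 ± 0.33. PTTG1, the securin released at anaphase, rose by 2.43 ± 0.34. Of the cell cycle list, 43 of 54 measured genes rose and 0 fell (adjusted over the list alone, 46 and 0; adjusted p = 0.16 with an estimated correlation). Epithelial and carcinoma genes were the one list called by camera with an estimated correlation: 19 of 27 measured genes rose and 0 fell (adjusted over the list alone, 21 and 0; adjusted p = 0.0068 with an estimated correlation). CLDN4, a tight junction protein, rose by 1.17 ± 0.17, EPCAM, an epithelial adhesion protein, by 1.18 ± 0.18, and KRT8, a keratin of simple epithelia, by 0.91 ± 0.14. That call was lost with the subject number as a replicate block (adjusted p = 0.13). For glycolysis, 13 of 18 measured genes rose and 0 fell (adjusted over the list alone, 14 and 0; adjusted p = 0.073 with an estimated correlation). ENO1, the glycolytic enolase, rose by 1.21 ± 0.13 and LDHA, which makes lactate, by 0.85 ± 0.11. Reference genes were not level either: 5 of 9 measured genes rose and 1 fell (adjusted over the list alone, 6 and 1; adjusted p = 0.095 with an estimated correlation), and GAPDH rose by 0.88 ± 0.13, in the same direction under each scaling tried.

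Many of the lung's own cell type genes fell. For type I cells, 10 of 14 measured genes fell and 0 rose (adjusted over the list alone, 11 and 1; adjusted p = 0.097 with an estimated correlation). CLIC5, a chloride channel family protein, fell by 2.86 ± 0.33 and EMP2, a membrane protein, fell by 2.00 ± 0.27. For alveolar type II cells and surfactant, 5 of 19 measured genes fell and 1 rose (adjusted over the list alone, 7 and 1; adjusted p = 0.24 with an estimated correlation). CLDN18, a tight junction protein of alveolar cells, fell by 3.01 ± 0.48 and LAMP3, a lamellar body protein, fell by 2.38 ± 0.48, while SFTPC, surfactant protein C, stood -1.64 ± 0.65 from adjacent lung and did not pass (adjusted p = 0.071). For endothelium, 24 of 28 measured genes fell and 0 rose (adjusted over the list alone, 25 and 0; adjusted p = 0.073 with an estimated correlation). TEK, the angiopoietin receptor, fell by 2.81 ± 0.28 and VWF, which binds platelets, fell by 2.18 ± 0.23. For resident lung fibroblasts, 14 of 16 measured genes fell and 0 rose (adjusted over the list alone, 14 and 0; adjusted p = 0.089 with an estimated correlation), and TCF21, a transcription factor of lung mesenchyme, fell by 2.80 ± 0.40. For smooth muscle and pericytes, 13 of 18 measured genes fell and 0 rose (adjusted over the list alone, 14 and 0; adjusted p = 0.10 with an estimated correlation), and MYL9, a smooth muscle myosin light chain, fell by 1.87 ± 0.23.

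Among the remaining large falls, SLC6A4, the serotonin transporter, fell by 3.87 ± 0.42, and FABP4, a lipid chaperone, fell by 3.56 ± 0.57. MFAP4, a microfibril protein, fell by 3.44 ± 0.53, FCN3, a complement lectin, fell by 3.38 ± 0.50, and ADIRF fell by 3.43 ± 0.49. SOSTDC1, a secreted BMP and WNT antagonist, fell by 3.10 ± 0.46 and VIPR1, a receptor for vasoactive intestinal peptide, fell by 2.94 ± 0.44. The alcohol dehydrogenases ADH1B and ADH1A fell, with changes of -2.97 ± 0.47 and -3.32 ± 0.54, but a second probe set of ADH1A, a near-identical gene to ADH1B, stood at 0.13 and did not pass.

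Among genes of immune and blood cells, the B cell genes that passed rose, while most others that passed fell. For B and plasma cells, 5 of 17 measured genes rose and 0 fell (adjusted over the list alone, 8 and 0; adjusted p = 0.30 with an estimated correlation), and CD79A, part of the B cell receptor, rose by 1.25 ± 0.28. For macrophages, 8 of 24 measured genes fell and 2 rose (adjusted over the list alone, 10 and 3; adjusted p = 0.45 with an estimated correlation): MMP12, macrophage elastase, rose by 2.06 ± 0.49, whereas MRC1, the mannose receptor, fell by 1.02 ± 0.27. For T and NK cells, 4 of 23 measured genes fell and 0 rose (adjusted over the list alone, 4 and 0; adjusted p = 0.61 with an estimated correlation), and IL7R, the interleukin 7 receptor, fell by 1.48 ± 0.30. For neutrophils and mast cells, 6 of 18 measured genes fell and 1 rose (adjusted over the list alone, 7 and 1; adjusted p = 0.24 with an estimated correlation). For red blood cells, 5 of 8 measured genes fell and 0 rose (adjusted over the list alone, 5 and 0; adjusted p = 0.11 with an estimated correlation), and HBB, a globin, fell by 1.69 ± 0.34. Immediate early genes, which respond within minutes to stimulation or stress, were also counted: 22 of 29 measured genes fell and 0 rose (adjusted over the list alone, 24 and 0; adjusted p = 0.15 with an estimated correlation). DUSP1, a MAP kinase phosphatase, fell by 2.13 ± 0.37, and KLF4, a transcription factor, fell by 1.52 ± 0.25.

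Some genes of energy metabolism, translation and protein handling rose. For ribosome biogenesis and translation, 14 of 24 measured genes rose and 0 fell (adjusted over the list alone, 18 and 0; adjusted p = 0.13 with an estimated correlation). For oxidative phosphorylation, 12 of 27 measured genes rose and 0 fell (adjusted over the list alone, 19 and 0; adjusted p = 0.19 with an estimated correlation). For the proteasome, 12 of 27 measured genes rose and 0 fell (adjusted over the list alone, 15 and 0; adjusted p = 0.17 with an estimated correlation). For the unfolded protein response and secretion, 10 of 22 measured genes rose and 1 fell (adjusted over the list alone, 12 and 1; adjusted p = 0.11 with an estimated correlation), and SSR4, of the translocon, rose by 1.29 ± 0.20. For the TGF-beta and BMP pathway, 13 of 32 measured genes fell and 0 rose (adjusted over the list alone, 14 and 2; adjusted p = 0.073 with an estimated correlation), and TGFBR2, a TGF-beta receptor, fell by 1.89 ± 0.32. Over all 36 lists, camera called 23 with a preset correlation of 0.01 and 1 with an estimated one. Fry, which asks whether a list's genes move one way on balance, called 11 lists up and 15 down.

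**Figure D1:**
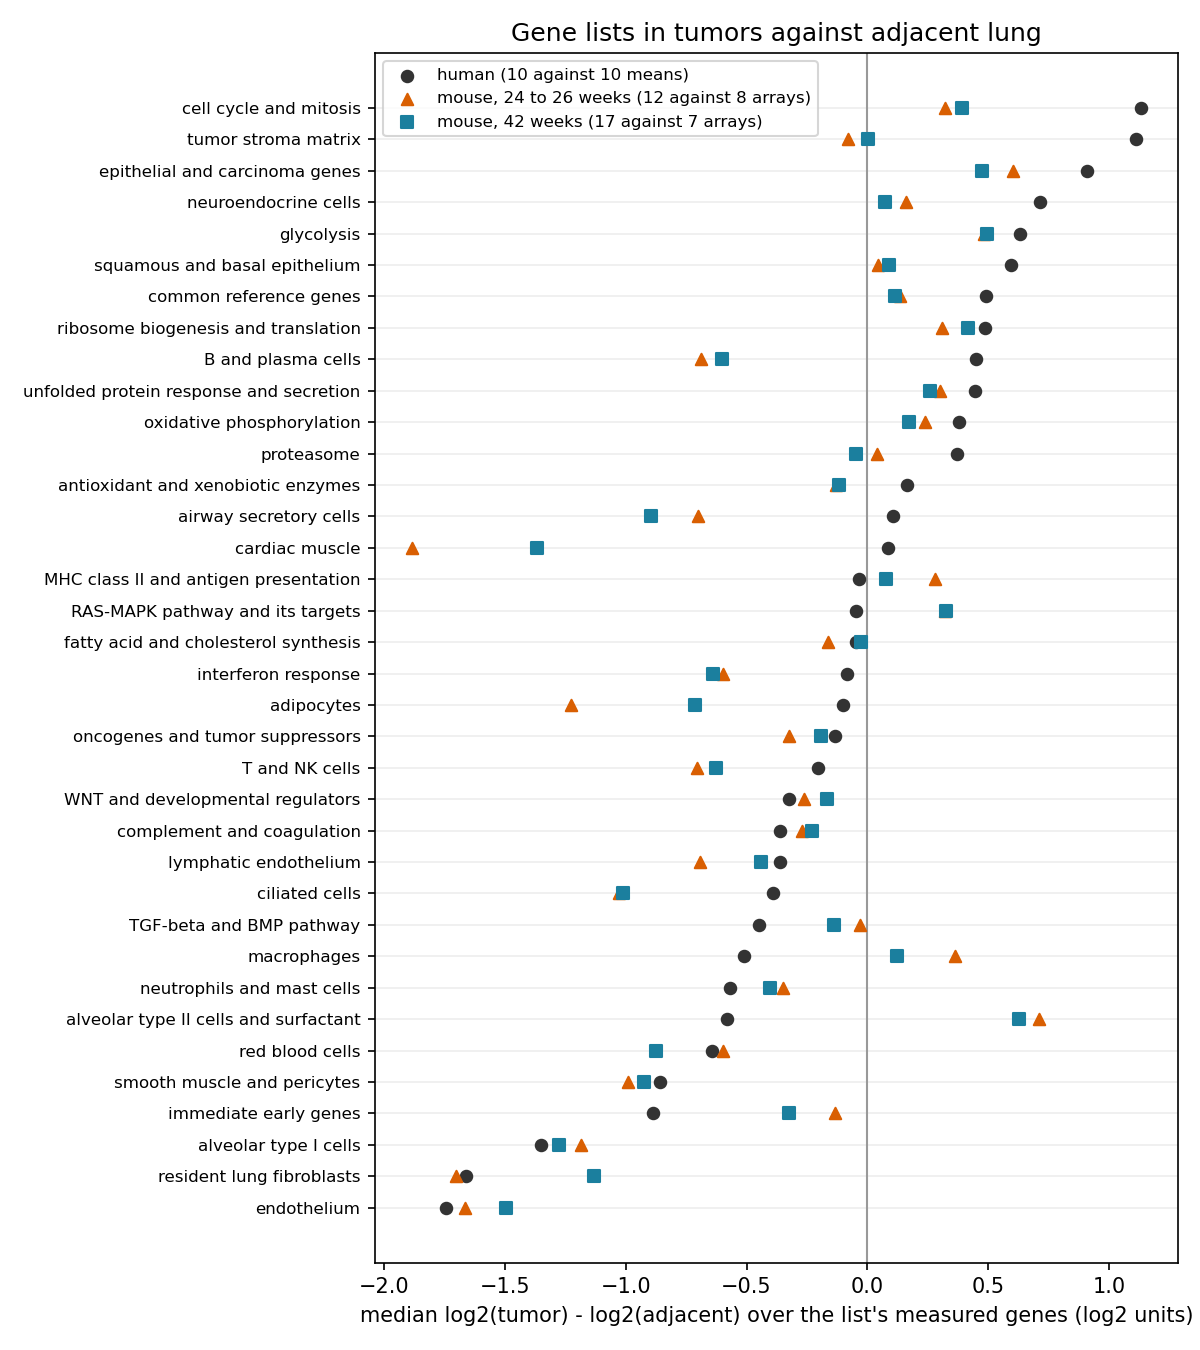
Median log2 difference of tumor minus adjacent lung over the measured members of each of the 36 gene lists (horizontal axis, log2 units), for human tumors and for mouse tumors at 24 to 26 and 42 weeks (points). Endothelial genes lie at -1.74, -1.67 and -1.49, while genes of alveolar type II cells lie at -0.58 in human tumors and at 0.71 and 0.63 in mouse tumors.

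Mouse tumors were set against adjacent lung at 24 to 26 weeks (12 against 8 arrays). Among the largest rises were those of Meg3, a maternally expressed noncoding RNA, and Dlk1, the imprinted gene beside it on chromosome 12. Meg3 rose by 5.46 ± 0.89, from 237 ± 394 to 8276 ± 4806 (SD, n = 8 and 12), and Dlk1 by 5.32 ± 0.78, from 208 ± 58 to 14790 ± 8999. In the mouse assembly GRCm38.p6 Dlk1 spans 109452485 to 109463336 and Meg3 109540996 to 109571729. Most measured alveolar type II genes rose, and most of vessels, resident fibroblasts, cilia and airway secretory cells fell. With all arrays none of these lists passed camera with an estimated correlation, as given below. Limma called 3277 of 8251 genes, 1629 higher and 1648 lower in tumors, with 223 and 525 changed at least 2-fold.

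Cldn2, a claudin that forms cation channels, rose by 4.24 ± 0.73 and Ereg, a ligand of the epidermal growth factor family, by 3.84 ± 0.53, from adjacent signals of 9.81 ± 2.12 and 7.26 ± 8.37 (SD, n = 8). The mitochondrial arginase Arg2 rose by 3.24 ± 0.40 and Ros1, a receptor tyrosine kinase, by 2.90 ± 0.49. Clu, the secreted chaperone clusterin, rose by 2.73 ± 0.36 and Fbp2, a fructose bisphosphatase, by 2.71 ± 0.58. The plasma protein genes Alb and Apoc1 rose by 2.96 ± 0.54 and 2.54 ± 0.39, Parm1 by 2.54 ± 0.43 and Bex4 by 2.54 ± 0.40. For alveolar type II cells and surfactant, 12 of 15 measured genes rose and 0 fell (adjusted over the list alone, 13 and 0; adjusted p = 0.080 with an estimated correlation). Dlk1 is a member of this list. Cebpa, a transcription factor of type II cells, rose by 1.47 ± 0.17, Ctsh, a protease that processes surfactant protein, by 1.80 ± 0.21, and Sftpb, surfactant protein B, by 0.71 ± 0.10. For epithelial and carcinoma genes, 17 of 23 measured genes rose and 1 fell (adjusted over the list alone, 17 and 1; adjusted p = 0.080 with an estimated correlation), and Hpn, a membrane serine protease, rose by 2.28 ± 0.27. For RAS-MAPK genes, 11 of 23 measured genes rose and 3 fell (adjusted over the list alone, 12 and 4; adjusted p = 0.18 with an estimated correlation), Ereg among those that rose.

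Of the 12 falls that the naming rule took at 24 to 26 weeks, 6 were in heart muscle genes. Myl7, the atrial myosin light chain, fell by 6.48 ± 0.73, from 3768 ± 2023 to 20.8 ± 11.6 (SD, n = 8 and 12). The heart muscle genes Myh6, Tnni3, Tnnc1, Csrp3 and Tnnt2 fell, with changes of -4.69 ± 0.61, -4.35 ± 0.56, -4.18 ± 0.49, -4.16 ± 0.53 and -3.73 ± 0.48. Of the cardiac muscle list, 8 of 12 measured genes fell and 2 rose (adjusted over the list alone, 8 and 2; adjusted p = 0.18 with an estimated correlation). Over the 15 adjacent arrays of both ages Myl7 ran from 43.4 to 8253. Reg3g, an antibacterial lectin, fell by 4.25 ± 0.72 and Bpifb1, secreted by airway cells, fell by 4.10 ± 0.64. Pon1, a paraoxonase, fell by 3.93 ± 0.44, Car3, a carbonic anhydrase, fell by 3.84 ± 0.61, and Bmp6, a bone morphogenetic protein, fell by 3.74 ± 0.44. Mfap4 fell by 3.76 ± 0.46, although its other probe set rose, by 0.58. Here 12 named genes had a mean under 50 in tumor or adjacent lung, so the size of their change depends on the number added to the signal. With 1 and 64 added in place of 16 the changes were: Ereg (5.7 and 2.44), Cldn2 (5.35 and 3), Ros1 (3.36 and 2.13), Alb (3.33 and 2.32), Car3 (-5.22 and -2.53), Csrp3 (-5.5 and -2.8), Tnnc1 (-5.43 and -2.85), Reg3g (-5.17 and -3.12), Myl7 (-7.36 and -5.26), Tnni3 (-5.21 and -3.23), Myh6 (-5.53 and -3.58) and Tnnt2 (-4.15 and -2.96). All 12 passed with either number.

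For endothelium, 25 of 29 measured genes fell and 0 rose (adjusted over the list alone, 26 and 0; adjusted p = 0.080 with an estimated correlation), and Kdr, a receptor of vascular endothelial growth factor, fell by 2.47 ± 0.22. For smooth muscle and pericytes, 11 of 15 measured genes fell and 2 rose (adjusted over the list alone, 11 and 3; adjusted p = 0.074 with an estimated correlation), and Myh11, smooth muscle myosin, fell by 3.55 ± 0.36. For ciliated cells, 7 of 8 measured genes fell and 0 rose (adjusted over the list alone, 7 and 0; adjusted p = 0.080 with an estimated correlation), and Foxj1, the master regulator of motile cilia, fell by 1.90 ± 0.32. Resident lung fibroblast genes were counted too: 14 of 18 measured genes fell and 1 rose (adjusted over the list alone, 15 and 1; adjusted p = 0.080 with an estimated correlation). For airway secretory cells, 6 of 11 measured genes fell and 0 rose (adjusted over the list alone, 7 and 1; adjusted p = 0.18 with an estimated correlation), and Cyp2f2, a P450 of club cells, fell by 2.22 ± 0.43. For alveolar type I cells, 9 of 10 measured genes fell and 0 rose (adjusted over the list alone, 9 and 0; adjusted p = 0.16 with an estimated correlation), and Hopx, a type I regulator, fell by 1.50 ± 0.24.

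Among immune genes of the T and NK cell list, 14 of 20 measured genes fell and 0 rose (adjusted over the list alone, 15 and 0; adjusted p = 0.18 with an estimated correlation), and Ccl5, a T cell chemokine, fell by 2.66 ± 0.39. For B and plasma cells, 9 of 15 measured genes fell and 1 rose (adjusted over the list alone, 9 and 2; adjusted p = 0.27 with an estimated correlation), and Ms4a1, the B cell antigen CD20, fell by 2.04 ± 0.33. For macrophages, 8 of 23 measured genes rose and 0 fell (adjusted over the list alone, 8 and 0; adjusted p = 0.29 with an estimated correlation), and Cd14, a coreceptor for lipopolysaccharide, rose by 1.88 ± 0.19. For the interferon response, 13 of 22 measured genes fell and 1 rose (adjusted over the list alone, 13 and 1; adjusted p = 0.18 with an estimated correlation), and Irf1, an interferon-induced factor, fell by 0.96 ± 0.13. Of the red blood cell list, 4 of 8 measured genes fell and 1 rose (adjusted over the list alone, 6 and 1; adjusted p = 0.18 with an estimated correlation), and Alas2, the first enzyme of heme synthesis in red cells, fell by 2.96 ± 0.44. For the cell cycle list, 22 of 51 measured genes rose and 3 fell (adjusted over the list alone, 23 and 3; adjusted p = 0.29 with an estimated correlation), and Cdc20 rose by 1.01 ± 0.15.

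Camera called 0 of 36 lists at 24 to 26 weeks with an estimated correlation, against 25 with the preset one, and fry called 10 up and 20 down. Without the Tq array the estimated correlation left 4 lists called: alveolar type II cells, ciliated cells, endothelium, and smooth muscle and pericytes (adjusted p = 0.035 each). That Tq array lay near adjacent lung, and without it 3534 genes were called. The AJ arrays shared 1 scan day, on which 3061 genes were called, and the LZ arrays of a second day gave 1609. With the scan day as a block 3577 genes were called, 3219 of them among the 3277, while LZ arrays alone gave 489, or 1464 without the Tq array. Meg3 stood 5.74 above adjacent lung on the first day and 7.26 on the second, Dlk1 5.22 and 6.58. Some falls were far smaller on the second day, with 2 adjacent and 4 tumor arrays: Reg3g stood at -5.39 and -0.91, Bpifb1 at -5.43 and -1.61 and Car3 at -4.60 and -1.61. Of the 18 genes named in this text that were called at this age and have another probe set, 9 had one that moved less than 0.5 times as far or the other way: Arg2 (0.26), Ereg (0.43), Lcn2 (0.59), Mfap4 (0.58), Mmp9 (-0.29), Pafah1b3 (0.09), Reg3g (-2.04), Thbd (-0.39) and Zbtb16 (0.09). Of the 73 genes named for this comparison, 34 lost their call among LZ arrays alone and 10 within the second day, of which 16 and 4 kept at least 0.75 of their change.

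At 42 weeks (17 against 7 arrays) the tumors again showed high Meg3 and Dlk1. Meg3 rose by 4.94 ± 0.88 and Dlk1 by 4.40 ± 0.77, the latter from 300.1 ± 123 to 12803 ± 11206 (SD, n = 7 and 17). Klf2, a flow-responsive factor of endothelium, fell by 3.56 ± 0.49, from 908 ± 182 to 113 ± 159. Hpgd, which breaks down prostaglandins, fell by 3.54 ± 0.50. Limma called 3168 genes, 1643 higher and 1525 lower in tumors, with 200 and 417 changed at least 2-fold.

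Ros1, Fbp2, Bex4, Arg2, Clu and Apoc1 rose at this age as well, by 3.39 ± 0.48, 3.08 ± 0.57, 2.85 ± 0.39, 2.74 ± 0.39, 2.47 ± 0.36 and 2.36 ± 0.38. Elf5, an epithelial transcription factor, rose by 2.58 ± 0.34 and Hgfac, which activates hepatocyte growth factor, by 2.52 ± 0.29. Igfals, a carrier of insulin-like growth factors in serum, rose by 2.43 ± 0.33 and Aass, a lysine breakdown enzyme, by 2.39 ± 0.35. Falls included Igfbp6 (-3.26 ± 0.56), Bmp6 (-3.12 ± 0.43), Pon1 (-2.92 ± 0.43), Myh11 (-2.91 ± 0.36) and Alas2 (-2.68 ± 0.44). Ogn, a small matrix proteoglycan, fell by 2.95 ± 0.49, Gria1, a glutamate receptor subunit, fell by 2.91 ± 0.36, Myzap fell by 2.85 ± 0.33 and Scn7a, a sodium channel, fell by 2.75 ± 0.43. Mfap4 fell by 2.71 ± 0.45, while its other probe set stood at 0.30. With 1 and 64 added to the signal the dim genes stood as follows: Ros1 (4.75 and 2.25) and Gria1 (-3.81 and -1.89).

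Of the endothelial list at 42 weeks, 26 of 29 measured genes fell and 1 rose (adjusted over the list alone, 26 and 1; adjusted p = 0.11 with an estimated correlation). The one that rose was Pecam1, an endothelial adhesion protein, by 0.72 ± 0.27, named after its values were seen because it was the exception. Its mean adjacent signal of 106.1 lay under the median signal of these arrays (167.7 to 200.6). With 1 and 64 added to the signal its change was 0.82 and 0.53. Eng, a TGF-beta coreceptor of endothelium, fell by 2.09 ± 0.20. For type II cells and surfactant, 10 of 15 measured genes rose and 0 fell (adjusted over the list alone, 12 and 0; adjusted p = 0.11 with an estimated correlation), and Lpcat1, which makes surfactant lipid, rose by 1.31 ± 0.17. For resident lung fibroblasts, 13 of 18 measured genes fell and 2 rose (adjusted over the list alone, 13 and 2; adjusted p = 0.22 with an estimated correlation): Pdgfra, a growth factor receptor, fell by 1.41 ± 0.21, but Pla2g1b, a secreted phospholipase, rose by 1.54 ± 0.21. In the ciliated cell list, 6 of 8 measured genes fell and 0 rose (adjusted over the list alone, 6 and 0; adjusted p = 0.11 with an estimated correlation). For T and NK cells, 14 of 20 measured genes fell and 0 rose (adjusted over the list alone, 14 and 0; adjusted p = 0.22 with an estimated correlation), and Cd3e, of the T cell receptor complex, fell by 2.22 ± 0.35. For the cell cycle list, 24 of 51 measured genes rose and 0 fell (adjusted over the list alone, 25 and 0; adjusted p = 0.25 with an estimated correlation). Cardiac muscle genes showed 7 members that fell and 1 that rose of 12 measured (adjusted over the list alone, 7 and 1; adjusted p = 0.31 with an estimated correlation). The one that rose was Myh7, the slow myosin heavy chain, by 1.67 ± 0.33.

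At 42 weeks camera called 0 of 36 lists with an estimated correlation and 22 with the preset one, and fry called 9 up and 20 down. Without the Tq array the ciliated and endothelial lists were called (adjusted p = 0.043 each), and 3427 genes. Within scan days 3 and 5, 1711 and 2591 genes were called, with the spread taken from all mouse arrays. Scan day 4 held 1 adjacent and 2 tumor arrays, so only the size of changes is given for it. The scan day block gave 3531, 3131 of them shared with the 3168. Dlk1 stood 5.48, 3.88 and 4.10 above adjacent lung on scan days 3, 4 and 5. Of the 56 genes named, 4 lost their call within scan day 3 and 1 within scan day 5. Another probe set moved less than 0.5 times as far or the other way for 10 of the 18 that have one: Arg2 (0.56), Gria1 (-1.04), Igfals (0.01), Lcn2 (0.48), Mfap4 (0.3), Mmp9 (-0.06), Pafah1b3 (-0.14), Pdgfra (0.21), Thbd (-0.57) and Zbtb16 (-0.94).

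**Figure D2:**
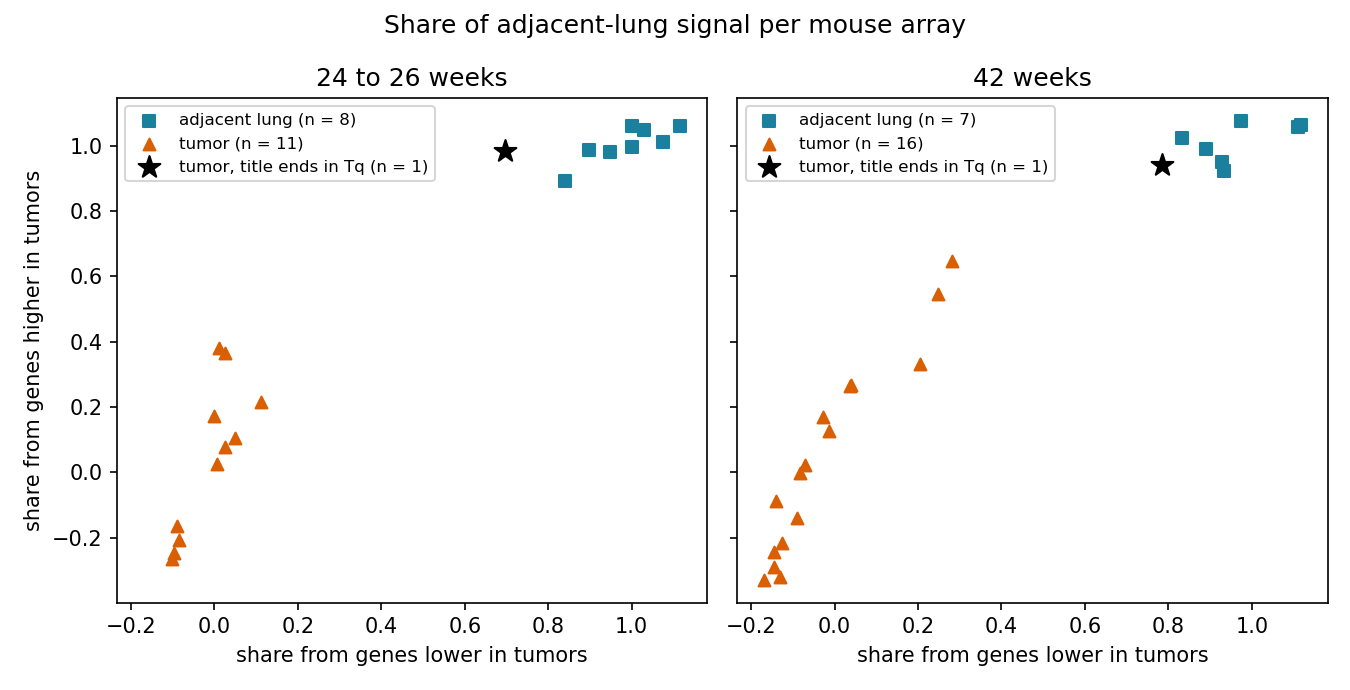
Share of adjacent-lung signal in each mouse array, as estimated from the genes that fell in tumors (horizontal axis, share) and from those that rose (vertical axis, share). By construction tumors without Tq center near 0 and adjacent arrays near 1. Single tumors without Tq reached 0.112 and 0.381 at 24 to 26 weeks and 0.282 and 0.648 at 42 weeks. The Tq arrays, left out of the fit, lie at 0.696 and 0.984 at 24 to 26 weeks and at 0.785 and 0.94 at 42 weeks.

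Whether the tumor change itself differed between the 2 ages was tested with an interaction term in limma. It called 0 of 8251 genes, with 647 under an unadjusted p of 0.05, and camera called 0 of 36 lists with an estimated correlation and 4 with the preset one, and fry 0. Across genes measured in both species the changes at the 2 ages had a Spearman rho of 0.832 and a Pearson r of 0.911. Of the 1477 such genes called at both ages, 1476 moved the same way. Genes are not independent replicates, so these values carry no p.

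Between 42 and 24 to 26 weeks, 332 genes differed in tumors (17 against 12 arrays), 200 higher and 132 lower at 42 weeks. Sdc4, a cell surface proteoglycan, rose by 0.90 ± 0.17, Cotl1, an actin-binding protein, by 0.76 ± 0.14, and Cdkn1a, a cell cycle inhibitor, fell by 1.18 ± 0.21. Agpat1 rose by 0.84 ± 0.15, Ago2, the slicer of RNA interference, by 0.71 ± 0.18, and Ube2s by 0.69 ± 0.16. Igh-VS107, Myl4 and Actg2 rose by 0.69 ± 0.19, 0.69 ± 0.16 and 0.66 ± 0.14. Jkamp fell by 1.42 ± 0.21, the nucleoporin Nup54 fell by 1.00 ± 0.24 and Ift20, of intraflagellar transport, fell by 0.92 ± 0.15. Pik3ca, a kinase of membrane lipids, fell by 0.89 ± 0.21. Rgs11, Banp and Chd8 fell, with changes of -0.82 ± 0.23, -0.78 ± 0.14 and -0.75 ± 0.13. Other probe sets of Cdkn1a (-0.2), Igh-VS107 (0.17), Pik3ca (-0.07) and Rgs11 (0.18) moved less than 0.5 times as far or the other way. Camera called 0 lists with an estimated correlation and 1 with the preset one, while fry called squamous and basal epithelium and WNT and developmental regulators up (adjusted p = 0.026 each). Age went with title prefix and scan day, since all AJ arrays were of 24 to 26 weeks. With the prefix as a block 12 genes were called, and among LZ arrays 10. Of the 16 genes named, 15 lost their call with the block, of which 4 kept at least 0.75 of their change and 11 kept under 0.5, and 15 lost it among LZ arrays (2 and 11). With the block and among LZ arrays they stood at: Sdc4 0.41 and 0.37, Agpat1 0.27 and 0.21, Cotl1 0.87 and 0.98, Ago2 0.04 and 0.17, Igh-VS107 0.30 and 0.14, Myl4 0.54 and 0.53, Ube2s 0.05 and 0.05, Actg2 0.32 and 0.05, Chd8 -0.32 and -0.22, Banp -0.73 and -0.60, Rgs11 -0.69 and -0.60, Pik3ca -0.22 and -0.19, Ift20 -0.45 and -0.36, Nup54 -0.75 and -0.69, Cdkn1a -0.35 and -0.21, Jkamp -0.58 and -0.55. Cotl1 held in both, with adjusted p = 0.0088 and 0.00055. The share of called genes that were higher at 42 weeks was 60.2%, but 21.8% with each array centered on its median and 42.2% with quantile normalization.

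In adjacent lung 319 genes differed between the ages (7 against 8 arrays), 161 higher and 158 lower at 42 weeks. Ago2 rose by 1.67 ± 0.25, Ddr2, a collagen receptor, by 1.46 ± 0.36, Cotl1 by 1.20 ± 0.19 and Agpat1 by 1.19 ± 0.21. Rap2b rose by 1.05 ± 0.16, Sdc4 by 0.95 ± 0.23 and H2-M9 by 0.97 ± 0.28. Fzd4, a WNT receptor, rose by 0.98 ± 0.23, but among LZ arrays it stood at -0.02. Jkamp fell by 1.84 ± 0.29, Dusp8, a MAP kinase phosphatase, fell by 1.39 ± 0.30, Pik3ca fell by 1.04 ± 0.28, and Kdr fell by 0.87 ± 0.25. Rab10, Brix1, Fancc and Tspan12 fell, with changes of -1.03 ± 0.20, -1.03 ± 0.23, -0.97 ± 0.24 and -0.84 ± 0.24. Camera called 0 lists with an estimated correlation and 1 with the preset one, and fry 0. Other probe sets of Brix1 (0.0), Fancc (-0.06), Fzd4 (-0.13), Pik3ca (-0.17) and Rap2b (-0.21) likewise moved less or the other way. The prefix block left 16 genes called and the LZ arrays alone 4. With that block 15 of the 16 named genes lost their call, of which 4 kept at least 0.75 of their change and 8 kept under 0.5, and among LZ arrays 16 lost it (2 and 12). With the block and among LZ arrays they stood at: Ago2 0.81 and 0.47, Ddr2 0.73 and 0.08, Cotl1 1.34 and 1.08, Agpat1 0.46 and 0.61, Rap2b 0.59 and 0.47, Fzd4 0.20 and -0.02, H2-M9 0.83 and 0.40, Sdc4 0.32 and 0.43, Tspan12 -0.91 and -0.59, Kdr -0.87 and -0.43, Fancc -1.07 and -1.06, Brix1 -0.72 and -0.48, Rab10 -0.32 and -0.19, Pik3ca -0.17 and -0.23, Dusp8 -0.71 and -0.53, Jkamp -0.77 and -0.86. Scaling moved the share of called genes that were higher from 50.5% to 37.1% with median centering and to 41.6% with quantile normalization. No scan day held adjacent lung of both ages, so scan day and age cannot be told apart there.

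Human and mouse tumors were compared over 4889 genes paired by symbol. The gene called higher in human tumors and at both mouse ages that led the naming rule was PHLDA2, an imprinted growth regulator, at 1.92, 1.88 and 1.67 log2 units in human, younger mouse and older mouse. LCN2, an iron-trapping lipocalin, stood at 1.35, 1.93 and 1.67, and CLDN3, a tight junction protein, at 1.82, 1.33 and 1.29. MMP12, MARCKSL1, HMGB3, EPCAM, NIPSNAP1, PAFAH1B3, KIF23, CKS1B and TPI1 completed the 12 higher genes of the naming rule. Among the lower genes, MFAP4 stood at -3.44, -3.76 and -2.71, and TNNC1, cardiac troponin C, at -2.64, -4.18 and -3.22. In mouse Tnnc1 is one of the heart muscle genes for which cardiac tissue in adjacent samples stays open. Its signal ran from 82.9 to 1894.4 over the 15 adjacent arrays. The lung mesenchyme factor TCF21 stood at -2.80, -2.92 and -2.53. Next came the endothelial genes CLDN5, PTPRB, TEK, RAMP2, THBD and CALCRL, with ZBTB16, FOXF1 and SMAD6, whose second human probe set stood at -0.95.

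In all, 441 genes were called the same way in the 3 comparisons, 172 higher and 269 lower. Lists drawn independently of each other would share 27.9 and 30.7. Taking the genes shared by both mouse ages as 1 list, chance with the human calls would give 93.9 higher and 109.9 lower. Opposite calls numbered 101. Of these, 48 were higher in human and lower in mouse tumors, among them the B cell gene CD79A, at 1.25, -1.31 and -1.22, and the protease MMP9, at 1.99, -1.64 and -1.69. The other 53 were lower in human and higher in mouse tumors, among them ROS1, at -1.16, 2.90 and 3.39. These examples of opposite genes were chosen after their values were seen, and the other mouse probe set of Mmp9 stood at -0.29 and -0.06. Independent lists would give 113 and 91.1. Across the paired genes the human change and the mouse change had a Spearman rho of 0.268 and a Pearson r of 0.305 at 24 to 26 weeks. At 42 weeks rho was 0.261 and r 0.305. Genes are not independent replicates here either.

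Several lists differed between species in their mean change over paired members, by a two-sided permutation test with 100000 relabelings and Benjamini-Hochberg adjustment over 36 lists. Alveolar type II genes stood at -0.53 in human and 1.21 in mouse tumors (adjusted p = 6.0e-05), above the adjacent level in 4 of 10 human and 29 of 29 mouse tumors. The list as fixed also holds Dlk1, which rose by 5.32 and 4.40 at the 2 mouse ages. Over all measured mouse members the means were 1.07 and 0.88, and the medians 0.71 and 0.63. The difference between species was not tested without Dlk1. Tumor stroma matrix stood at 0.98 and -0.06, and B and plasma cell genes at 0.58 and -0.51 (adjusted p = 6.0e-05 each). Cell cycle genes stood at 1.15 and 0.38 (adjusted p = 0.00015), macrophage genes at -0.53 and 0.18 (adjusted p = 0.0018). The unadjusted p of the type II, stroma and B cell lists was 1e-05, the smallest these relabelings can give. For endothelium, at -1.64 and -1.49, the difference did not pass (adjusted p = 0.57).

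**Figure D3:**
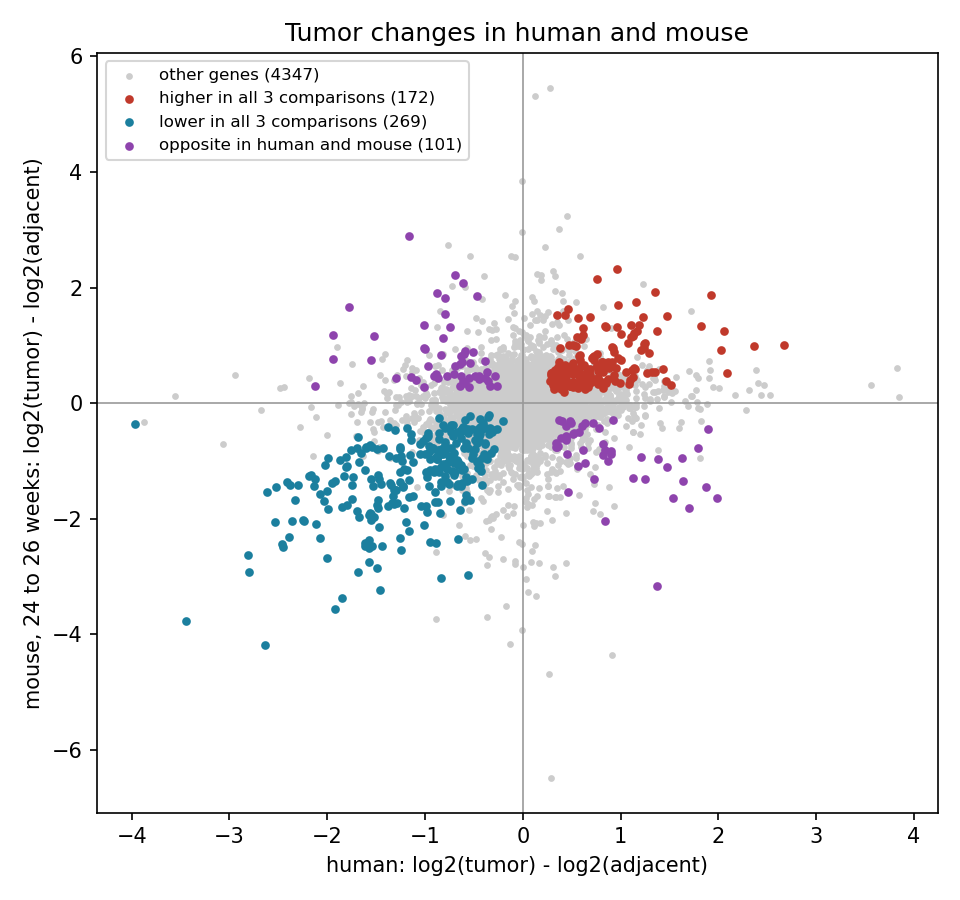
Tumor minus adjacent log2 difference in human (horizontal axis, log2 units) against mouse at 24 to 26 weeks (vertical axis, log2 units) for 4889 genes paired by symbol, 1 point per gene. Colored points are the 172 genes called higher and the 269 called lower in human and at both mouse ages, and the 101 called in opposite directions.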

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

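The tests of species differences, of the Tq arrays as adjacent lung under a tumor label, and of unnamed probe sets were chosen only after the data were seen. Besides, 2 rules were also added after the result was seen: the allowance of 1 jackknife SE around the bounds in the test of age against title prefix, and the rule that markers of which most lie under the median signal of adjacent lung decide nothing. They left open 6 results that the bounds alone had decided, as given below. The bounds of the other tests were written before their result.

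Several gene lists changed differently in human and mouse tumors, by the permutation test of the difference of mean log2 changes (human minus mouse, each with an adjusted p under 0.05 over 36 lists). Lists lower in human than in mouse were alveolar type II cells (-1.75), macrophages (-0.71), immediate early genes (-0.65), alveolar type I cells (-0.57), RAS-MAPK genes (-0.36) and TGF-beta and BMP genes (-0.25). The type II list holds Dlk1, as given above. Lists higher in human were cardiac muscle (1.51), ciliated cells (1.15), B and plasma cells (1.09), tumor stroma matrix (1.05), cell cycle (0.78) and red blood cells (0.74). T and NK cells (0.54), the interferon response (0.53), the proteasome (0.37), antioxidant enzymes (0.34), reference genes (0.19) and oxidative phosphorylation (0.18) were higher as well. Species goes with array type here, and the probe sets differ, so species and platform cannot be told apart. For the cardiac list, heart tissue in the mouse adjacent samples also stays open, as given below.

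Probe sets without a single gene symbol entered no comparison above, and limma called 288 of 1603 of them in human, 395 of 1589 in mouse at 24 to 26 weeks and 400 at 42 weeks.

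For each named gene in groups of up to 10 samples, the gap of the highest or lowest sample to the nearest one, as a share of the group's range, was set against Dixon's critical value. It was passed in 22 of 310 tests, where chance alone passes about 1 in 20. In human adjacent lung (10 means) the lowest value stood apart for FABP4 (0.4701), FCN3 (0.707), IL7R (0.5941), SLC6A4 (0.5936), SMAD6 (0.5068), TPI1 (0.4898), VIPR1 (0.6663). There the highest value stood apart for PTGES (0.6008), PTPRB (0.524), TFAP2A (0.4763). In human tumors (10 means) the highest value stood apart for NIPSNAP1 (0.4663). In mouse adjacent lung at 24 to 26 weeks (8 arrays) the lowest value stood apart for Csrp3 (0.5517), Dlk1 (0.6104), Kif23 (0.6022), Ptprb (0.5791), Tpi1 (0.5567). There the highest value stood apart for Acvrl1 (0.6168), Bmp6 (0.7894). In mouse adjacent lung at 42 weeks (7 arrays) the lowest value stood apart for Eng (0.5784), Phlda2 (0.5834). There the highest value stood apart for Meg3 (0.8525), Mmp12 (0.6623).

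The first pattern is that the mouse Tq arrays, 1 per age, lay near adjacent lung, and that more genes were called without them. Genes that fell in tumors gave the Tq array a share of adjacent signal of 0.696 at 24 to 26 weeks and 0.785 at 42 weeks, and genes that rose gave 0.984 and 0.94, while the other tumors reached at most 0.381 and 0.648. A mixture with adjacent lung needs both shares high and alike, and the lowest share, 0.696, met the first need while the shares at 24 to 26 weeks differed by more than the 0.2 set beforehand. Adjacent lung under a tumor label needs all 4 shares within the range of the adjacent arrays, and 2 of the 4 were. Both explanations therefore stay open, as does a kind of tumor sample that the labels do not describe, which was not tested.

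The second pattern is that heart muscle genes were lower in mouse tumors than in adjacent lung, with a median difference of 1.607 log2 units over the 12 measured genes of the cardiac list, adjacent minus tumor. Skeletal muscle markers differed by a median of -0.089, under the bound that spoke against skeletal muscle, but 6 of 7 lay under the median signal and they went both ways (Acta1 1.67, Pvalb -0.52), so skeletal muscle stays open. In 2 of 15 adjacent arrays the list mean lay above every tumor array, as a few adjacent samples that carry cardiac tissue would give, but the list holds Myh7 and Sln, which were higher in tumors (-1.37 and -0.54, adjacent minus tumor), and by Myl7 alone 8 of 15 lay above every tumor without Tq, so how many samples carry it stays open. The ventricular Myl2 read 0.00223 of the signal of Myl7, under the bound of 0.05 that spoke against ventricular tissue. Myh7, the slow myosin heavy chain, ran opposite to the pattern, while Myh6, of both chambers, went with it (3.72, adjacent minus tumor). The ventricular Myl3 went with the pattern (0.99, adjacent minus tumor) but was dim, at 33.9 ± 27.8 in adjacent lung and 7.17 ± 11.85 in tumors (SD, n = 15 and 29). The atrial Myl4 and Nppa differed by only 0.52 and 0.39. Ventricular tissue is left open because Myl2, at 7.63 ± 2.91 (SD, n = 15), lay near the floor, where a silent gene and a probe set that does not respond look alike, and heart muscle of the pulmonary veins was not tested.

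The third pattern is that genes called between ages may follow the AJ or LZ title prefix, or age. Over the 332 genes called in tumors (median change 0.462), LZ minus AJ at 24 to 26 weeks in adjacent lung had a median of 0.105 in the direction of the age change (jackknife SE 0.099, exact permutation p = 0.214), and age within LZ adjacent lung gave 0.231 (SE 0.083, exact permutation p = 0.0278). Over the 319 genes called in adjacent lung (median change 0.569), LZ minus AJ in tumors without the Tq arrays gave 0.108 (SE 0.046, exact permutation p = 0.0394) and age within LZ tumors 0.134 (SE 0.06, permutation p = 0.00454). By the bounds alone, 0.5 of the median change for and 0.25 of it against, 0.231 spoke for age and the other 3 values against their explanation, but with 1 SE allowed none passed its bound, so prefix and age cannot be told apart for these genes, while over all genes AJ and LZ arrays of 24 to 26 weeks differed in 155 in tumors (a Tq array among the LZ arrays) and 20 in adjacent lung. With the prefix as a block and no Tq arrays the median change was 0.308 with a median SE of 0.149 in tumors (SE 0.119 without) and 0.425 with 0.16 in adjacent lung (SE 0.144 without), and most calls ended. Without Tq arrays, AJ arrays were scanned on day 1, LZ arrays of 24 to 26 weeks on day 2 and those of 42 weeks on days 3 to 5. In these tests neither prefix nor age can therefore be told apart from scan day. The p of 0.0278 is the smallest that its 36 splits can give.

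Other splits of the samples into groups of the same sizes were fitted, 100 for each result with the real one included. The real split alone reached its count, 1 of 100, for human tumors (1991 called, next 768), mouse tumors at 24 to 26 weeks (3277, next 3112) and at 42 weeks (3168, next 1292), and for age in tumors (332, next 182) and in adjacent lung (319, next 6). Random groupings of the arrays thus seldom gave such counts. For age the splits exchanged arrays across title prefix and scan day, so they cannot tell age from either. The split with 3112 kept all but 1 of the 8 adjacent arrays together. For the difference of tumor changes between ages (limma called 0 genes, 647 at an unadjusted p under 0.05) the real count is 0, which all 100 splits reach by necessity (highest 1), so the splits say nothing about chance there. A rank correlation with human as high as the real one came in 2 of 100 relabelings at 24 to 26 weeks (0.268, highest other 0.274) and in 3 of 100 at 42 weeks (0.261, highest other 0.275), the real one included. That is under the bound of 5 of 100, but other relabelings reached higher values, 1 of them at 42 weeks with 1 called gene, so the rank correlation speaks only weakly against chance. The higher value at 24 to 26 weeks came from the split with 3112 called genes. The highest at 42 weeks kept 5 of the 7 adjacent arrays together. The covariance with the human changes, which also grows with their size, was highest for the real labels at both ages. It was 0.125 at 24 to 26 weeks (next 0.123) and 0.111 at 42 weeks (next 0.0789).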

How the results depend on the processing

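Pairing is not stated in the labels, so the human fit had no block. Tumor and adjacent means of the same number correlated by 0.0833 on average after removal of the tissue means, against -0.00911 for other numbers, and 3 of 10 pairs passed 0.1, while 7 of 10 tumor means were best matched by their own number, where chance gives about 1. With the subject number as a replicate block (a paired fit) 1953 human genes were called, 1809 of them among the 1991. The human count stayed within 1.5 times under its 13 alternatives (1491 to 2616), and the difference of tumor changes between ages was 0 under all 14. Human scan days were not in the files, so that alternative was not run.

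Values that moved by more than 1.5 times follow; the cause was not tested unless one is given. At 24 to 26 weeks LZ arrays alone called 489 genes, 1464 without the Tq array and 1609 within scan day 2, on fewer arrays. At 42 weeks scan days 3 and 4 called 1711 and 387, also on fewer arrays. Age in tumors gave 500 genes with arrays centered on their median, 602 with the scan day as a block, 12 with the prefix as a block (27 without Tq arrays) and 10 among LZ arrays (20 without Tq arrays). Age in adjacent lung gave 490 with the scan day as a block, 16 with the prefix (47 without Tq arrays) and 4 among LZ arrays (8 without Tq arrays). The scan day block compares ages only through 1 day, on which the only tumor of 24 to 26 weeks was a Tq array. Under it Ago2 (-0.22), Agpat1 (-0.07), Sdc4 (-0.05), Ube2s (-0.42), Cdkn1a (0.14), Ift20 (0.55), Pik3ca (0.50) and Rgs11 (0.09) reversed in tumors, and Ddr2 (-0.50), Rap2b (-0.03), Sdc4 (-0.20), Brix1 (0.09), Pik3ca (0.52) and Rab10 (0.37) in adjacent lung. Fzd4 reversed among LZ arrays (-0.02, with or without the Tq arrays).

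The rank correlation with human rose to 0.365 and 0.357 over genes above the median signal on both platforms. Whether low signal over background is the reason was not tested. Genes called the same way in all 3 comparisons numbered 441 against 101 opposite calls, or 97 against 10 when a 2-fold change was also asked. Of list calls over the 3 tumor comparisons, 1 with an estimated correlation, the preset correlation gave 70, the replicate block (human alone) 0, leaving out the mouse Tq arrays 7 and fry 85, while 18 of 36 lists differed between species. Fry asks another question than camera. Of the values of named genes under the alternatives, 888 of 893 kept direction and call in human, 1244 of 1301 and 745 of 778 in mouse at the younger and older age, and 133 of 208 and 114 of 190 for age in tumors and in adjacent lung. Named genes were mostly chosen for large changes or small p in these same arrays, so these shares do not stand for all called genes.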

Other observations

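Further gene groups of human tumors were mixed or mostly did not pass. Of the airway secretory list, 2 of 9 measured genes fell and 1 rose (adjusted over the list alone, 4 and 1; adjusted p = 0.61 with an estimated correlation): AGR2, a disulfide isomerase of mucus cells, rose by 1.36 ± 0.34, while SCGB1A1, the main club cell secretion, fell by 3.07 ± 0.63. The list's median was 0.11 and its mean -0.31. For WNT and developmental regulators, 11 of 31 measured genes fell and 5 rose (adjusted over the list alone, 12 and 7; adjusted p = 0.23 with an estimated correlation), and SOX4, a progenitor factor, rose by 1.27 ± 0.21. For antioxidant and xenobiotic enzymes, 6 of 28 measured genes fell and 3 rose (adjusted over the list alone, 6 and 4; adjusted p = 0.75 with an estimated correlation), with a median of 0.16 and a mean of -0.06. GPX3, a secreted peroxidase, fell by 2.38 ± 0.31. For complement and coagulation, 6 of 20 measured genes fell and 0 rose (adjusted over the list alone, 6 and 0; adjusted p = 0.24 with an estimated correlation). For oncogenes and tumor suppressors, 8 of 28 measured genes fell and 0 rose (adjusted over the list alone, 8 and 0; adjusted p = 0.15 with an estimated correlation), and CAV1, caveolin, fell by 2.62 ± 0.43. For cardiac muscle, 4 of 13 measured genes fell and 0 rose (adjusted over the list alone, 4 and 1; adjusted p = 0.29 with an estimated correlation), with a median of 0.09 and a mean of -0.31. Squamous and basal genes counted as follows: 3 of 11 measured genes rose and 0 fell (adjusted over the list alone, 4 and 0; adjusted p = 0.29 with an estimated correlation), and SFN, an epithelial cell cycle regulator, rose by 1.21 ± 0.28. Neuroendocrine genes gave few calls: 2 of 11 measured genes rose and 0 fell (adjusted over the list alone, 2 and 0; adjusted p = 0.61 with an estimated correlation). In the RAS-MAPK list, 4 of 28 measured genes fell and 3 rose (adjusted over the list alone, 4 and 3; adjusted p = 0.89 with an estimated correlation), with a median of -0.05 and a mean of 0.00714. In the ciliated cell list, 1 of 6 measured genes fell and 0 rose (adjusted over the list alone, 1 and 0; adjusted p = 0.45 with an estimated correlation). In the lymphatic endothelium list, 2 of 7 measured genes fell and 0 rose (adjusted over the list alone, 4 and 1; adjusted p = 0.24 with an estimated correlation). In the adipocyte list, 2 of 6 measured genes fell and 0 rose (adjusted over the list alone, 2 and 0; adjusted p = 0.24 with an estimated correlation). In the fatty acid and cholesterol list, 2 of 25 measured genes fell and 1 rose (adjusted over the list alone, 1 and 0; adjusted p = 0.83 with an estimated correlation). MHC class II and antigen presentation genes and interferon genes gave 1 lower and 0 higher of 14, and 1 lower and 1 higher of 25. Adjusted over the list alone both gave 0, with adjusted p = 0.85 and 0.92 with an estimated correlation.

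Further lists were counted in mouse tumors at 24 to 26 weeks, none of which passed camera with an estimated correlation. For glycolysis, 11 of 15 measured genes rose and 2 fell (adjusted over the list alone, 12 and 2; adjusted p = 0.18 with an estimated correlation), and Ldha rose by 1.31 ± 0.15. Fatty acid and cholesterol genes went both ways: 8 of 25 measured genes fell and 6 rose (adjusted over the list alone, 9 and 6; adjusted p = 0.76 with an estimated correlation). Fasn, the fatty acid synthase, rose by 0.91 ± 0.13 and Acsl4, which activates fatty acids, by 0.98 ± 0.13, while Idi1, of sterol synthesis, fell by 2.29 ± 0.31. MHC class II and antigen presentation genes were split too: 8 of 16 measured genes rose and 5 fell (adjusted over the list alone, 8 and 5; adjusted p = 0.67 with an estimated correlation). H2-Ab1, a class II chain, rose by 0.64 ± 0.10 and Psmb10, an immunoproteasome subunit, fell by 0.72 ± 0.12. Antioxidant enzymes included a rise of Hmox1, heme oxygenase, by 1.10 ± 0.14, and a fall of Gpx3, with a change of -1.42 ± 0.20: 14 of 31 measured genes fell and 5 rose (adjusted over the list alone, 14 and 8; adjusted p = 0.24 with an estimated correlation). In the TGF-beta and BMP list, 14 of 34 measured genes fell and 7 rose (adjusted over the list alone, 14 and 8; adjusted p = 0.12 with an estimated correlation), and Acvrl1, an endothelial receptor kinase, fell by 1.71 ± 0.21. In the WNT and developmental list, 15 of 35 measured genes fell and 7 rose (adjusted over the list alone, 16 and 7; adjusted p = 0.18 with an estimated correlation), and Tbx3, a lung mesenchyme factor, fell by 2.52 ± 0.29.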
